A study of Arabidopsis thaliana with 4 samples.

How the data were processed

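H3K4me2 was measured in Arabidopsis thaliana Col-0 seedlings grown without treatment, per the labels' protocols, for 10 to 11 days in liquid medium at 22 °C with a photoperiod of 16 hours and light of 100 µE per square metre and second. Per the labels' protocols, 15 µg of immunoprecipitated DNA and 15 µg of input DNA were used per array, and the DNA was amplified and directly labelled with Cy3 and Cy5. The labels place 4 arrays in 1 group with 2 replicates, each hybridised in both dye orientations.

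The deposited value table holds 1 column per array, with values on both sides of 0 that were treated as log ratios. Their log base, direction, background correction and normalization are not given in the sources used here. No scanner intensities were used here, so signal over background could not be examined. The deposited columns of a dye swap were identical in every feature, so each pair was taken as 1 profile. The deposited medians differed between replicates, so the values had not been centred to a common median. Of 21800 features, 21761 had plate and well names and 39 had other names, all of them empty. A further 33 named wells were empty, which left 21728 probes. A gene table of 38312 genes (assembly TAIR10.1) matched 2 feature names, both of them empty features, so no probe was tied to a gene.

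Each replicate was centred on its median without loess or quantile normalization. A design fixed before the data were examined foresaw log2 ratios of immunoprecipitate over input from 4 separate arrays. The unstated base and direction and the identical columns of each dye swap changed this to a fit of 2 profiles in deposited units. Each probe was tested two-sided against 0 with limma 3.58.1 (R 4.3.3) in a model with an intercept only, with moderated variances and Benjamini-Hochberg adjustment at 0.05 over all probes. The prior degrees of freedom were estimated at 117, an estimate that is poorly determined with 1 residual degree of freedom per probe.

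The fit was tested on simulated data with 21728 probes, 200 of them changed, in 20 runs per setting. With the same spread for all probes, 40.4% of changes of 0.5 and 99.9% of changes of 1 were recovered, and 4.24% of calls were false on average. With a spread that varied between probes, 37.9% and 99.95% were recovered and 12.4% of calls were false, which is above the nominal 0.05. Few probes were changed in these simulations, whereas most measured probes were called. These shares of false calls therefore need not hold for the measured data. The number of runs and the varying spread were chosen after a first single run had also given too many false calls. With simulated means like those measured, 17 of 17343 calls had the wrong sign. These means already held noise and the simulated spread was the same for all probes, so this count may be too low.

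Planned comparisons of genes with transposable elements, of heterochromatic regions of chromosome 4 with its arms, of positions within genes, of gene lengths and of fixed gene lists were not analysed here, because they need gene names or positions for the probes. The rule for named probes, fixed beforehand, takes the 5 highest and the 5 lowest probes past the threshold with the same sign on all arrays; 2 of each are printed by name. The comparisons of plate series, plates and wells were chosen after the data had been seen.

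Plate medians were taken per replicate and averaged. A first definition of the low blocks ended a run at a plate number without probes, and it was changed after the result was seen so that such a number no longer ends a run. Correlations between wells were computed on replicate means with 2000 bootstrap samples for 95% intervals. Positions of the block edges minimised the squared deviations from 2 levels, with intervals from 1000 bootstrap samples of the residuals in blocks of 12 probes. Wells were ordered along plate rows, with 96 wells per plate. Densities used a Gaussian kernel with a bandwidth of 0.1, and mixtures of normal distributions were fitted by expectation maximisation. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The alternatives covered centring, scaling, threshold, a minimum effect of 0.2, a mixture model, the prior degrees of freedom, the definition of blocks, and leaving out each replicate where a value remained.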

Results

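Dimethylation of lysine 4 of histone H3 (H3K4me2), a chromatin mark generally found along genes, was profiled in whole seedlings of Arabidopsis thaliana, accession Col-0, at an age of 10 days. Chromatin immunoprecipitated with an antibody against the mark was hybridised together with its own input DNA on 2-colour tiling arrays. The series served to map the mark as part of a reference epigenome of the seedling. It held 4 arrays, a technical dye swap for each of 2 replicates called I and II. Both columns of each dye swap held identical values for all 21800 array features (0 features differed), so each swap was counted as 1 profile and n was 2. Values were deposited for 21728 probes, and 72 features were empty on all 4 arrays. Precision was limited by this number of arrays. The labels did not say whether I and II came from separate cultures, so p-values measured only the spread between these samples, which may be technical. For single probes, limma took this spread mostly from all probes pooled.

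The values were log ratios of both channels with an unstated base. Arrays of opposite dye orientation carried the same sign, so the values had been turned to a common direction before deposit, but the deposited values did not settle whether a positive value meant more immunoprecipitate or more input. The deposited medians were -0.02 in replicate I and 0.47 in replicate II, an offset of 0.49. Each replicate was therefore centred on its own median, and every value that follows is higher or lower than the median probe in deposited log-ratio units. No fold change is given. Probes are named here by plate series, plate number and well, since the files used here paired them with neither genes nor positions.

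The probes were spread broadly and unevenly around the median. The most common value lay above it, at 0.51 in replicate I and 0.63 in replicate II. With a kernel bandwidth of 0.1, both replicates had further, lower peaks below the median, at -1.58 and -0.88 in replicate I and at -1.70 and -0.88 in replicate II, and replicate II had another at -0.06. A model of the replicate means with 3 normal components had a lower Bayesian information criterion than models with 1 or 2. Its components were centred at -1.70 with 9.19% of the probes, at -0.89 with 31.2% and at 0.53 with 59.6%. The lowest peak was shallow in replicate I, where the peak at -0.88 was higher (density 0.268 against 0.259) and where a bandwidth of 0.2 left no separate peak under -1. In replicate II the peak at -0.88 was also slightly higher than the lowest (density 0.247 against 0.246).

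**Figure D1:**
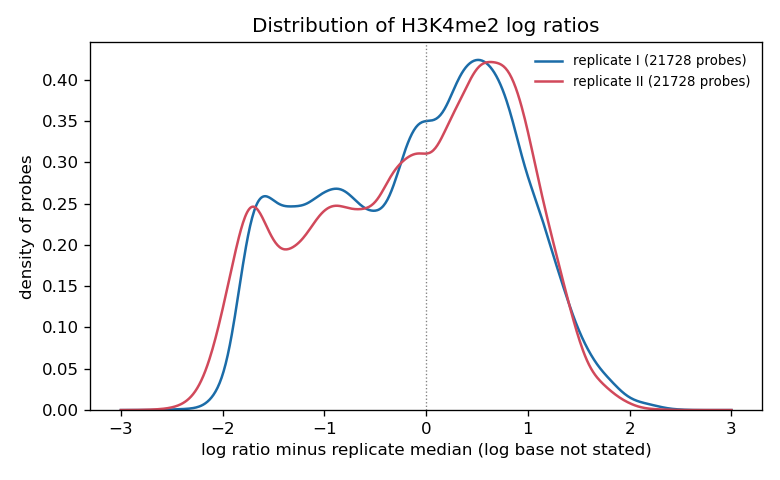
Density of the log ratios of 21728 probes after subtraction of each replicate's median, in deposited log-ratio units of unstated base, for replicate I (blue) and replicate II (red). Both curves are highest above the median, at 0.51 and 0.63, and both have smaller peaks below it, the lowest at -1.58 and -1.70.

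Most probes differed from the median by more than the spread between replicates. With limma and Benjamini-Hochberg adjustment at 0.05, 8752 probes (40.3%) were higher than the median, 8727 (40.2%) were lower and 4249 (19.6%) did not pass the threshold. The median size was 0.76 among the higher probes and -1.09 among the lower ones, so the lower side reached further. The smallest values called were 0.30 and -0.30. The near-equal split followed from centring on the median: centred on the main mode, 3035 probes were higher and 12391 lower, and without centring the numbers were 8115 and 5980. A mixture with 2 components placed 12178 probes in its upper and 4009 in its lower component, at a posterior of at least 0.95. Membership of a component is another measure than a difference from the median, so these are not counts of higher or lower probes. The call therefore separates probes from the median probe, not marked from unmarked sequence.

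The highest probe was TB17H12, at 2.28 ± 0.027 (SD, n = 2; limma adjusted p = 9.4e-28), followed by TB18A01 at 2.20 ± 0.083 (SD, n = 2; limma adjusted p = 7.2e-27). These occupy the last well of plate 17 and the first well of plate 18 in the TB series. The 5 highest probes ranged from 2.17 to 2.28. The lowest were TA53H07, at -2.40 ± 0.019 (SD, n = 2; limma adjusted p = 7.3e-29), and TA28E08, at -2.39 ± 0.094 (SD, n = 2; limma adjusted p = 7.3e-29). The 5 lowest ranged from -2.30 to -2.40 and all lay in the TA series. The limma standard errors of the named probes lay between 0.143 and 0.144, whatever their own SD, because the variance was mostly pooled over all probes. These p-values therefore do not follow from the SD printed beside them, and their size depends on the poorly determined prior degrees of freedom.

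Both replicates gave nearly the same profile. Across the 21728 probes, which are not independent replicates, Pearson's r was 0.953 and Spearman's rho 0.949. A total of 20010 probes (92.1%) had the same sign in both, and 65 (0.299%) were called although their signs differed. The difference between replicates had a standard deviation of 0.30 across probes, against 0.95 for the replicate means.

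The plate series differed in level. The 99 plates of the TA series (A plates, 9326 probes) had a median of -0.38 ± 0.01 (SD, n = 2), with 30.1% of probes higher and 52.2% lower than the array median. The 100 plates of the TB series (B plates, 9588 probes) had a median of 0.34 ± 0.02 (SD, n = 2), with 52.8% higher and 24.1% lower. The 27 plates of the TC series (C plates, 2403 probes) were the lowest, at -0.84 ± 0.04 (SD, n = 2). The 4 plates of the PD series were at 0.06 ± 0.05 and the single plate of the TD series at 0.29 ± 0.08 (SD, n = 2 each). B plates exceeded A plates by 0.70 in replicate I and by 0.75 in replicate II, a mean of 0.72 ± 0.03 (SD, n = 2). A sign-flip test with 2 replicates cannot give a two-sided p below 0.5. Without the low blocks described next, the difference was 0.39.

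Plates with low medians formed 3 long blocks of consecutive plates. These were plates 21 to 30 and 37 to 51 of the A series and plates 17 to 30 of the C series, where plate 26 held no probes. Together they made up 38 of the 231 plates. Their medians were -1.29 ± 0.07, -1.63 ± 0.10 and -1.62 ± 0.08 (SD, n = 2 each), and 82.1%, 94.97% and 97.3% of their probes were lower than the array median. Over all 3358 probes inside the blocks the median was -1.57 ± 0.10, against 0.22 ± 0.02 for the 18370 probes outside, a difference of -1.79 ± 0.11 (SD, n = 2). The blocks held 3102 of the 8727 probes called lower, while 5625 lay outside them, among these TA53H07, the lowest probe of all. Blocks were defined, after the plate medians had been seen, as at least 5 consecutive plates with a mean plate median under -1. When the plates were shuffled within their series 1000 times, the longest run had 9 plates against 15 observed (permutation p = 0.001, one-sided, the smallest that these shuffles can give). With plate means in place of medians, plates 21 to 30 of the A series no longer formed a block. Some plates of the blocks held few probes, such as 60 in plate 22 and 42 in plate 39 of the A series and 59 in plate 17 of the C series. Plates 40 to 51 of the A series were complete. Most plates outside the blocks were complete too, but plate 13 of the C series held 34 probes and plate 4 of the PD series 29. Whether missing probes go with low values was not tested.

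Levels differed between stretches of the A plates, whose limits were chosen by eye after the plate medians had been seen. Plates 1 to 20 had a median of 0.34 ± 0.02, and plates 31 to 36, between the low blocks, -0.13 ± 0.05 (SD, n = 2 each). After the second block the medians were -1.01 ± 0.02 in plates 52 to 59, -0.35 ± 0.03 in plates 60 to 69 and 0.14 ± 0.02 in plates 70 to 79 (SD, n = 2 each). Plates 80 to 99 were at -0.003 ± 0.03 (SD, n = 2). In the C series, plates 0 to 13 had a median of 0.37 ± 0.01 (SD, n = 2), in contrast to the low block that begins at plate 17. The plate numbers between 13 and 17 held no probes, so the change itself was not observed. Plates within a stretch did not hold 1 level, as plate 80 of the A series was at -0.74 and plate 81 at 0.55. No block was found among the B plates.

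**Figure D2:**
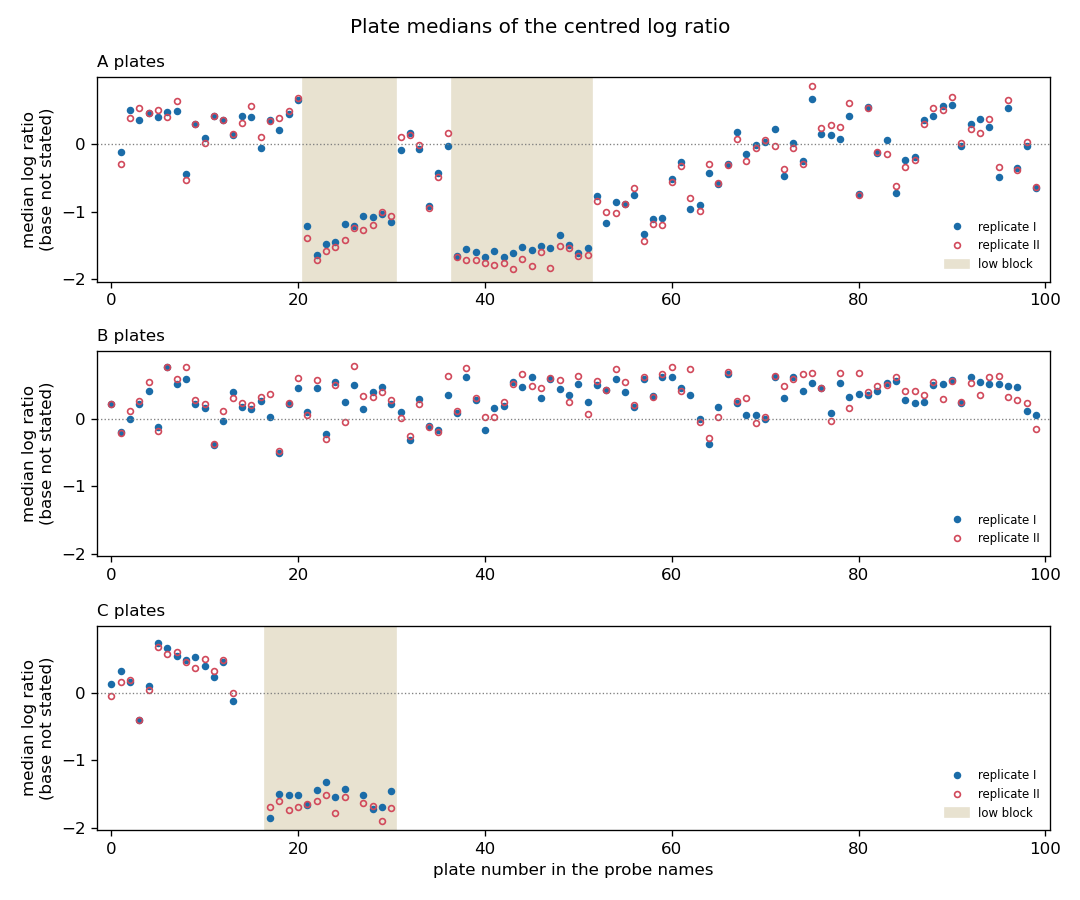
Median centred log ratio of each plate (vertical axis, deposited log-ratio units of unstated base) against the plate number in the probe names, for the A, B and C plates, with filled blue points for replicate I, open red points for replicate II and shading for the low blocks. The shaded plates 21 to 30 and 37 to 51 of the A series and 17 to 30 of the C series have mean medians under -1, as do plates 53 and 57 to 59 of the A series, which are not shaded.

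Probes with consecutive numbers had similar values. In the B plates, which held no low block, values of consecutive wells along a plate row correlated across probes with r = 0.684, and the correlation declined to 0.411 at a distance of 2 wells, 0.255 at 3 wells, 0.0782 at 12 wells and 0.0216 at 96 wells. The last well of a plate and the first well of the next correlated about as closely as wells in a row, with r = 0.678 (95% bootstrap interval 0.529 to 0.799, 99 pairs). Wells of the same column in adjacent rows, which lie 12 numbers apart, had r = 0.0894 (95% bootstrap interval 0.0687 to 0.110). Probes called higher formed 1170 runs of consecutive wells in the B plates, with a mean length of 4.32 probes and a longest run of 33, against a mean of 2.11 and a longest run of 27 when the probes were shuffled 200 times. Probes called lower formed 782 runs with a mean length of 2.95 probes and a longest run of 22, against a shuffled mean of 1.32 and a longest shuffled run of 9.

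**Figure D3:**
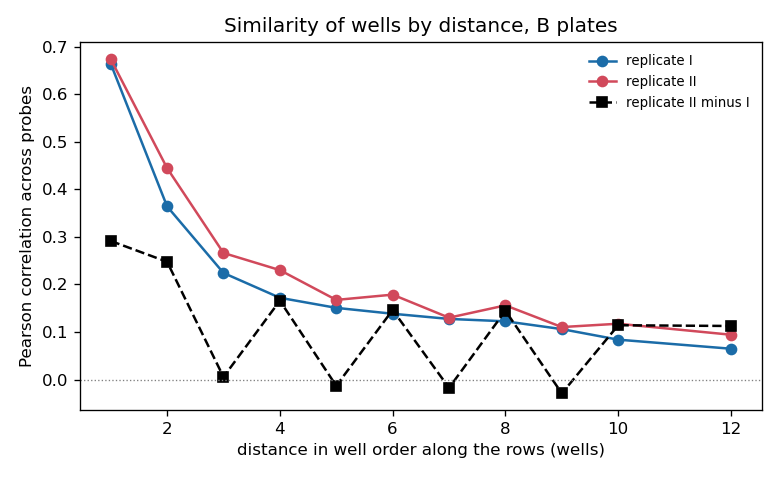
Pearson correlation across probes of the B plates (vertical axis) against the distance in wells along the plate rows (horizontal axis), for replicate I (blue), replicate II (red) and the difference, replicate II minus replicate I (black squares, dashed). Similarity of the values falls steadily with distance in replicate I. In replicate II it falls less evenly and rises slightly at 6, 8 and 10 wells, such as from 0.167 at 5 wells to 0.178 at 6 wells. Among the distances shown from 2 to 12 wells, the difference has a higher correlation at even than at odd ones, such as 0.248 at 2 wells and 0.00546 at 3 wells. It is highest at 1 well, at 0.291.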

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

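Of 44 alternatives, 35 left a result within 1.5 times its count or within the spread between replicates, and 9 moved it. The alternatives for plates, wells and blocks, for the column parity and for the prior degrees of freedom were chosen after seeing the data. Centring on the main mode lowered the probes above to 3035 and those above inside the low blocks from 131 to 36. A mixture with 2 components, which fitted less well than 3, placed 4009 probes in its lower and 12178 in its upper component. These numbers count component membership at a posterior of at least 0.95, not differences from the median. Fixed prior degrees of freedom of 10 and 4 gave 8604 and 8572 probes above. The neighbour correlation in the B plates was 0.0937 down the columns, 0.667 with Spearman's rho and 0.664 to 0.674 with 1 replicate left out, against 0.684. B plates exceeded A plates by 0.62 with means and by 0.39 without the low blocks, against 0.72. The cause was not tested, except that another centre shifts all values alike and that the blocks themselves lower the A plates. The number of plates in low blocks stayed between 28 and 41. Not run were an estimated duplicate correlation, 4 arrays taken as independent, a dye term, single arrays left out and 1 dye orientation alone, which identical swap columns make void, and probes with complete values, since none was partly empty. Leaving out a replicate gives no test of single probes, and the comparisons of genes and regions could not be run. Signal over background was not examined.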

Other observations

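The tests of closeness on the plate, of odd and even columns, of the A, B and C plates together and of the other 3 block edges, and the intervals of all edges, were chosen only after the result was seen; the other tests had their predictions written beforehand, on patterns already noticed in these data.

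The low blocks were not uniformly low. They held 131 probes (3.90%) called higher than the array median, in 54 runs of consecutive probes, of which 34 had at least 2 probes and the longest had 8. Plates 21 to 30 of the A series held 96 of these probes, plates 37 to 51 held 28 and the C block held 7. Of the 96, the 12 in plate 21 all lay before the drop fitted within that plate, which is described next. Centred on the main mode, 36 such probes were left.

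If whole plates had failed in printing or amplification, each drop to a low block would lie on a plate border, within 5 probes. A 2-level fit was made at the 4 edges of the A blocks. It placed 3 of 4 edges more than 5 probes from the border in both replicates, against this prediction. With intervals, brought in afterwards, 1 of 4 lay clear of the border. That drop lay 44 probes into plate 21 of the A series in both replicates (95% bootstrap intervals 23 to 53 and 29 to 54). There, 22 of the 42 probes before it and 48 of the 48 after it in that plate were called lower. This argues against failure of whole plates as the cause of all edges. At the other 3 edges the intervals reached to within 5 probes of the border (0 lay clear of it). Block 37 to 51 was fitted to start 18 probes before plate 37 in both replicates. Of these, 18 of 18 were called lower, against 20 of 78 in the rest of plate 36. Its end was fitted 17 and 18 probes into plate 52, where 16 of 17 were lower, against 54 of 79 after them. Block 21 to 30 ended 4 probes before the border. Since the intervals reach the border, plate failure stays open at these edges. The edges of the C block were not fitted, because the plate numbers next to it held no probes. Plate failure was therefore not tested for the C block and stays open there. If the probes had given only noise, the replicates would not correlate inside the blocks, but r was 0.918 and rho 0.749 across their 3358 probes, and without the probes called higher, a choice made afterwards, r was 0.871 and rho 0.831 in plates 21 to 30, 0.858 and 0.689 in plates 37 to 51, and 0.774 and 0.587 in the C block. A bias of single probes shared by all arrays, such as repeated sequence, stays open, and the design, with 1 group, gives no biological contrast for the blocks.

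Similarity of neighbouring wells was set against closeness on the plate. Wells joined across a plate border correlated more than wells in adjacent rows, by 0.588 (95% bootstrap interval 0.437 to 0.709), which argues against closeness on the plate. They differed from consecutive wells in a row by -0.00717 (95% bootstrap interval -0.158 to 0.114). This is what probe numbers that follow the order along a chromosome would give, so that order is a candidate explanation. Overlap of neighbouring probes or of sheared fragments was not tested. It would itself need consecutive probes to be neighbours in the genome, so it is not a rival to such an order.

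As a hypothesis, the plates may run along 1 chromosome from end to end. Plate medians were correlated with the share of protein-coding genes in as many windows of gene order, over 5 chromosomes and 2 directions. For the 199 A and B plates the highest r was 0.780, for chromosome 2 (95% bootstrap interval 0.705 to 0.836), and chromosome 4 had 0.625; with the sign of the ratio turned, the highest was 0.352. Over all 10 choices of chromosome and direction, the highest r after circular shifts was 0.790, for chromosome 4. The prediction of a value above every shift was therefore not met. Chromosome 2, itself picked as the highest of the 10 choices, lay slightly above its own shifts, which reached 0.772. With plates 0 to 13 of the C series added, the highest r was 0.741, for chromosome 4 (95% bootstrap interval 0.644 to 0.812), with 0.708 for chromosome 2, 0.785 after shifts and 0.342 as the highest with the sign turned. The first reading of the A and B result counted it against the hypothesis; the interval was brought in afterwards, and since it holds the shifted value in both tests, they leave the hypothesis open. Without the plates under -1 the values fell to 0.357 and 0.257, so the relation rests mostly on the low plates, and neither the chromosome nor the direction of the ratio is settled.

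The difference between replicates alternated with distance in the B plates. Its correlation across probes was 0.291 at 1 well, 0.248 at 2 wells, 0.00546 at 3 wells and 0.166 at 4 wells, so immediate neighbours did not follow the alternation. Splitting each plate into odd and even columns explained 8.25% of the within-plate variance of the difference, against at most 4.57% for random splits of the 12 columns into equal sets. This split restates the alternation that prompted it, so whether wells of odd and even columns were spotted or scanned apart stays open, and no biological explanation was tested. With the difference of each plate and column parity removed, 8216 probes were called higher and 8397 lower.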
